A study of Mus musculus with 13 samples.

How the data were processed

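RNA from the aorta of male C57BL/6 mice was measured on 13 arrays with biotin-labelled total RNA, extracted with QIAzol and purified on columns per the labels. The mice were young (3 to 4 months in the study's design text, 3 months in the extraction protocol) or aged (12 months). They carried either an intact mineralocorticoid receptor (MR-intact, labelled wild type) or a deletion of that receptor, which per the study's design text is limited to smooth muscle cells (knockout). Groups were taken from the genotype and age labels of each sample: 3 young MR-intact, 3 young knockout, 4 aged MR-intact and 3 aged knockout arrays. Replicates were numbered within each group and the numbers only name an array.

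The authors deposited log2 expression values, 1 per gene and array, in a workbook at full precision and again in a second table rounded to 2 decimals. Per the submitters' processing notes these came from RMA (background correction, quantile normalization and a summary over probes), with the packages affy and limma also named. Versions of those tools, the array platform, the chip definition and the hour of tissue collection are not given in the sources used here. The workbook also holds the authors' mean log2 value per group, and per the file headers a signed fold change (a score that is negative where the first group is lower) and an unadjusted p-value for 4 comparisons. Those columns carry the authors' own test, whose design is not given in the sources used here, and they were used only for a side-by-side check. Features carry Entrez gene IDs: of 21225, 20768 matched the mouse gene table of assembly GRCm38.p6, which was used for names only, and 457 kept the name given with the deposited values; 2545 symbols were updated. No coordinates are given, since no genome build is named.

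All fits here used the 21225 deposited log2 values without further scaling or filtering, in R 4.3.3 with limma 3.58.1 (lmFit and eBayes with the default prior). All 13 arrays entered 1 model with a coefficient for each group, so that the small groups shared an estimate of the spread (residual degrees of freedom 9, prior degrees of freedom 3.41). The median gene SD was 0.148 in aged knockout and 0.09 to 0.114 in the other groups. SEs and p-values of contrasts with aged knockout arrays thus rest partly on tighter groups and may be too small. The contrasts were aging in MR-intact aorta, aging in knockout aorta, knockout against MR-intact in young and in aged aorta, the mean of both knockout contrasts, and the difference of aging between genotypes (the interaction). Tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes of a contrast. The contrasts, tests, gene lists, naming rule and most alternatives were fixed before the data were examined. No batch is named in the labels. The letter in the sample titles was A for every aged and B for every young array, and its meaning is not given. An effect of whatever it marks could not be told apart from age. No pair of arrays within a group held identical values.

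For each contrast the text names, among called genes whose arrays did not overlap between the groups, the 12 with the largest log2 change in each direction, leaving out predicted genes, clone names, olfactory and vomeronasal receptors, microRNAs and small nucleolar RNAs. Where under 5 genes were called, the 10 with the smallest p are given and said not to pass. Some genes that met the rule are not reported here. Nr3c2 and Nr3c1 are given outside this rule, with up to 4 members of each list described.

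A total of 36 gene lists with at least 5 measured members was tested with camera at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists of a contrast. Each list was also tested with a correlation estimated from the data, which is the stricter setting, and with fry, which asks whether the members move on balance in one direction and compares them with no other genes. The lists covered corticosteroid receptor targets, contractile smooth muscle, fibrillar collagen and cross-linking, elastic fibre, basement membrane, matrix proteases and inhibitors, integrins and focal adhesion, ion channels and calcium handling, vasoactive receptors, the renin-angiotensin-aldosterone system, oxidant and antioxidant enzymes, TGF-beta and BMP signalling, cytokines and chemokines, complement, interferon response, senescence, cell cycle, circadian clock, immediate early genes, osteochondrogenic genes, oxidative phosphorylation, the unfolded protein response and lipid metabolism. Marker lists covered white and brown adipocytes, endothelium, fibroblasts, macrophages, T lymphocytes, B lymphocytes and plasma cells, skeletal muscle, cardiac muscle, Schwann and neuronal cells, mesothelium, erythroid cells and platelets, and liver. Some lists share members: contractile smooth muscle and cardiac muscle share 1, and macrophage and complement share 3.

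Simulated data took each gene's mean over all arrays and its residual spread pooled over the groups, with noise independent between genes. The wider spread of the aged knockout arrays and genes that move together were thus not simulated, so recovery and false calls may differ in the real data. The model was tested in 5 such simulations of 21225 genes with 200 changed. At a 1.5-fold change it recovered 69.9% of changed genes for aging in MR-intact aorta, 67.8% for aging in knockout aorta and 74.9% for the knockout in aged aorta. At a 2-fold change the shares were 92.8%, 89.3% and 94.3%, and at a 4-fold change 98.5%, 98.5% and 99.1%. False calls made up 5.13%, 5.86% and 5.1% of calls in these contrasts. The number of arrays limits the precision.

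Alternatives were an intensity trend with a robust prior, a second quantile normalization, centring of each array on its median, removal of the dimmest tercile of features, array weights, the rounded values, a fit of only the groups compared, blocks taken from numbers in the sample titles, and leaving out each array in turn. Chosen after seeing the data were fits without aged knockout replicates 1 and 2 (which leave 1 aged knockout array, assumed to vary like the other groups), fits with the mean of the B lymphocyte list as a covariate, the array-by-array runs of the list tests and of the slope of aging genes, and a fit without the block of the arrays used for the title digit block. Single values in small groups were compared with exact permutation tests.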

Results

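Expression in mouse aorta was measured on 13 arrays, 3 young MR-intact, 3 young knockout, 4 aged MR-intact and 3 aged knockout. The knockout lacks the mineralocorticoid receptor, the nuclear receptor for aldosterone encoded by Nr3c2, in smooth muscle cells, the contractile cells of the arterial wall. Young mice were 3 to 4 months old and aged mice 12 months. The study asked how vascular RNA changes with age and how the smooth muscle receptor bears on that change. Each array gave a log2 value for 21225 genes, with array medians between 5.85 and 5.97. The labels do not say that the arrays of a group came from separate animals, so p-values measure the spread between these samples, which may be technical.

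Nr3c2 (Entrez 110784) was lower in knockout than in MR-intact aorta at both ages. Its log2 level was 6.66 ± 0.04 (SD, n = 3) in young MR-intact and 6.26 ± 0.17 (SD, n = 3) in young knockout aorta, and 7.01 ± 0.21 (SD, n = 4) in aged MR-intact and 6.31 ± 0.24 (SD, n = 3) in aged knockout aorta. The young MR-intact arrays read 6.68, 6.62 and 6.69, and the young knockout arrays 6.26, 6.09 and 6.42. The aged MR-intact arrays read 7.12, 6.86, 6.80 and 7.24, and the aged knockout arrays 6.14, 6.22 and 6.58. Every knockout array therefore lay below every MR-intact array. Over both ages the difference was -0.55 (two-sided exact permutation p = 0.00143 over 700 regroupings within age). In aged aorta it was -0.69 (two-sided exact permutation p = 0.0286), and in young aorta -0.40 (two-sided exact permutation p = 0.1, the smallest that 3 against 3 arrays allow). Over all genes the limma test did not call it, with adjusted p = 0.0599 in aged aorta, 1 in young aorta and 0.175 for the mean of both. With age Nr3c2 changed by 0.35 in MR-intact (limma adjusted p = 0.449) and by 0.06 in knockout aorta (limma adjusted p = 0.905). The difference of these changes was -0.29 (limma adjusted p = 0.686). Nr3c1 (Entrez 14815), the glucocorticoid receptor, differed between genotypes by 0.04 in young and 0.01 in aged aorta, and changed with age by 0.07 in MR-intact and 0.04 in knockout aorta. Other aortic cells keep Nr3c2, and the position of the probes relative to the deleted exons is not given in the sources used here, so a probe outside the deleted part would check nothing.

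**Figure D1:**
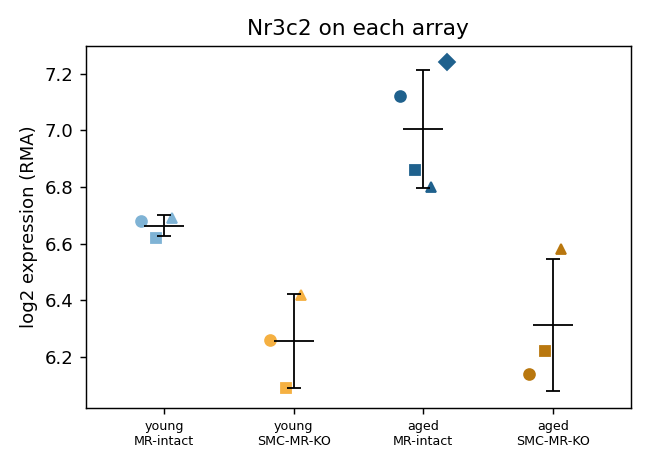
Log2 expression of Nr3c2 on each array, by group; bars mark the mean and error bars 1 SD (n = 3, 3, 4 and 3), and marker shape gives the replicate number. All knockout arrays, 6.09 to 6.58, sit below all MR-intact arrays, 6.62 to 7.24.

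The aged knockout arrays stood apart from the rest and from each other. Principal component 1, with 34.7% of the variance, placed them at 44.5, 35.2 and 14.4, and all other arrays between -16.1 and 1.5. Pairs of aged knockout arrays correlated at 0.983 to 0.99 across genes, against 0.992 or more within the other groups, and their median gene SD was 0.148 against 0.114 in aged MR-intact, 0.096 in young knockout and 0.09 in young MR-intact aorta. Immune markers moved with these arrays: the B lymphocyte and plasma cell list averaged 8.76, 7.22 and 7.04 on aged knockout replicates 1, 2 and 3, and 5.42 to 5.90 on the aged MR-intact arrays. Young knockout replicate 3 also read high at 6.84. Liver markers averaged 7.45 on aged knockout replicate 2, against 5.63 to 6.21 on aged MR-intact arrays. The albumin gene Alb read 9.82 on that array, but also 8.33 on aged MR-intact replicate 3, 8.16 on young knockout replicate 1 and 7.95 on young MR-intact replicate 1. The catecholamine enzyme gene Th read 7.43 on it and 4.33 to 6.46 on the other arrays. Skeletal muscle markers were uneven among young arrays, at 7.68, 7.1 and 5.28 in MR-intact and 5.64, 5.6 and 7.24 in knockout aorta.

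**Figure D2:**
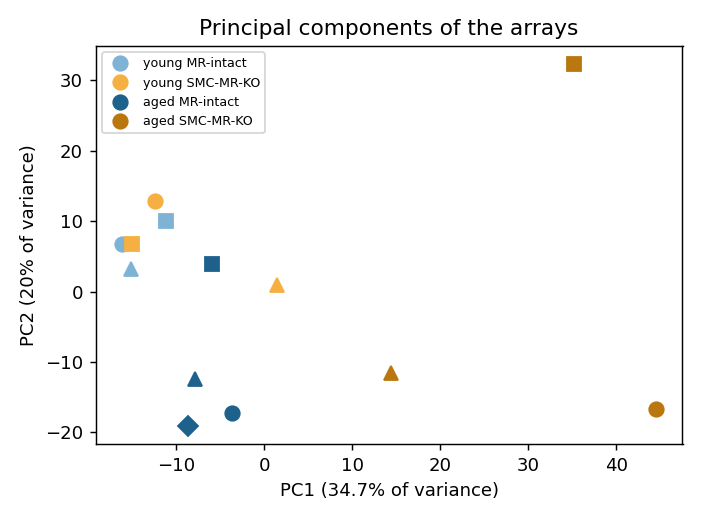
Principal components 1 and 2 of the log2 values of the 13 arrays, in component units with the share of variance on each axis; colour gives the group and marker shape the replicate. Aged knockout replicates 1 and 2 lie at 44.5 and 35.2 on component 1, while no array outside that group exceeds 1.5.

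The fibrillar collagen genes Col1a1, Col1a2 and Col3a1 fell with age in MR-intact aorta, and genes including Ube2ql1, Ibsp and Ccl8 rose. Col1a1 (Entrez 12842), a chain of type I collagen, fell by 1.08 on the log2 scale (SE 0.10, limma adjusted p = 0.000787, n = 4 and 3), from 10.09 ± 0.23 to 9.01 ± 0.08. Col3a1, the type III collagen chain, changed by -0.77 (SE 0.08, limma adjusted p = 0.00239), and Col1a2, the other type I chain, by -0.71 (SE 0.09, limma adjusted p = 0.00679). Lox, which cross-links collagen and elastin, changed by -0.69, and Adamts2, which trims procollagen, by -0.59. Among the other genes that fell were Cish, a SOCS-family inhibitor of cytokine signalling, at -1.71, and Adamtsl2, Lrg1, Bace2, Fbln1 and Slc4a10 at -0.78 to -0.49. Ube2ql1 (Entrez 76980), which resembles ubiquitin-conjugating enzymes, rose by 1.76 (SE 0.20, limma adjusted p = 0.00359), from 5.86 ± 0.23 to 7.62 ± 0.45. Ibsp (Entrez 15891), bone sialoprotein, rose by 1.07 (SE 0.12, limma adjusted p = 0.00328), and Capn13 (Entrez 381122), a calpain protease, by 1.02 (SE 0.09, limma adjusted p = 0.000787). Ccl8, a monocyte chemokine, rose by 1.63, the growth factor binding protein Igfbp2 by 1.5, the guidance cue Sema3e by 1.23, the cadherin Cdh9 by 1.32 and apolipoprotein D (Apod) by 1.0. Dpp10, an auxiliary subunit of potassium channels, rose by 1.31, the calcium channel subunit gene Cacna2d3 by 1.18, the adhesion gene Nfasc by 1.08 and gamma-synuclein (Sncg) by 1.03.

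In all, 50 genes were called for aging in MR-intact aorta, 38 higher and 12 lower, with a median absolute log2 change of 0.78. All 50 had arrays that did not overlap between the groups; of all 21225 genes 10.9% were separated in this way, where chance gives 5.71%. The count was 29, 32 and 33 without aged MR-intact replicates 1, 3 and 4, 28 and 14 without young MR-intact replicates 1 and 2, and 489 (276 higher, 213 lower) with array weights. Without young MR-intact replicate 3 it was 104, with the balance turned to 34 higher and 70 lower. Of the 50, 4 had a lower group mean below the lower quartile of every array compared (3.89 to 4.06), among them Ibsp (3.70), Capn13 (3.47) and Dpp10 (3.44), so how far these low levels stand above background is not known. Of the 24 genes that met the naming rule, 9 were called whichever array was left out, among them Ube2ql1, Sema3e, Ibsp, Capn13, Apod, Col1a1, Col3a1 and Adamts2; of the other 15, between 3 and 14 lost the call with any one array gone, the most without young MR-intact replicates 1 (10) and 2 (14), and 5, 3, 6 and 6 without aged MR-intact replicates 1 to 4 and 6 without young replicate 3.

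By group, 4 of 35 fibrillar collagen and cross-linking genes fell with age in MR-intact aorta (10 when adjusted over the list alone), with a median of -0.14 and a camera adjusted p = 1.25e-13; adjusted p = 0.0772 with an estimated correlation. Of 25 osteochondrogenic genes 2 rose, Ibsp and the osteoclast inhibitor gene Tnfrsf11b, the latter by 0.88 (3 higher when adjusted over the list alone). Their median was 0.09 (camera adjusted p = 0.00524; adjusted p = 0.124 with an estimated correlation). Of 34 cytokine and chemokine genes 1 rose, Ccl8 (5 when adjusted over the list alone), with a median of 0.14 (camera adjusted p = 4.3e-05; adjusted p = 0.279 with an estimated correlation). The 24 macrophage markers had a median of 0.19 with 0 called and 2 higher when adjusted over the list alone (camera adjusted p = 3.04e-05; adjusted p = 0.338 with an estimated correlation). Basement membrane genes had a median of -0.12 with 0 of 20 called and, adjusted over the list alone, 1 higher and 7 lower (camera adjusted p = 0.000615; adjusted p = 0.294 with an estimated correlation). Elastic fibre genes had a median of -0.10 with 1 of 20 called, Fbln1 (1 higher and 4 lower when adjusted over the list alone; camera adjusted p = 0.00303; adjusted p = 0.475 with an estimated correlation), and the median was -0.06 without aged MR-intact replicate 2 and -0.05 without young MR-intact replicate 3. Among 36 matrix proteases and inhibitors Mmp3, stromelysin, rose by 0.94 and Adamts2 fell (2 higher and 5 lower when adjusted over the list alone; camera adjusted p = 0.0763). Contractile smooth muscle genes had a median of 0.06 with 1 of 30 called, Sncg (1 higher and 1 lower when adjusted over the list alone; camera adjusted p = 0.464). Corticosteroid receptor targets had a median of -0.05 with 0 of 25 called (2 lower when adjusted over the list alone; camera adjusted p = 0.058).

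Lists of muscle, endothelial and fibroblast markers were lower with age in the same arrays at the preset correlation, but none was called with an estimated correlation. The 19 skeletal muscle markers had a median of -1.45 and the 16 cardiac muscle markers -1.22, with 0 called in each list and, adjusted over the list alone, 16 and 11 lower (camera adjusted p = 6.07e-14 and 2.82e-13; adjusted p = 0.294 and adjusted p = 0.251 with an estimated correlation). Among MR-intact arrays both lists were highest on young replicates 1 and 2, with cardiac list means of 7.77 and 7.59 against 5.76 on replicate 3. Without young replicate 1 the medians were -0.86 and -0.78, and without young replicate 3 the cardiac median was -1.92. Endothelial markers had a median of -0.23 with 0 of 22 called (3 lower when adjusted over the list alone; camera adjusted p = 1.6e-07; adjusted p = 0.338 with an estimated correlation). Fibroblast markers had a median of -0.09 with 0 of 20 called (3 lower when adjusted over the list alone; camera adjusted p = 0.000352; adjusted p = 0.38 with an estimated correlation). T lymphocyte markers had a median of 0.10 (camera adjusted p = 0.366), and B lymphocyte and plasma cell markers a median of -0.02 but a mean of 0.23 and an upward test (camera adjusted p = 0.452). Of 36 lists camera called 15 at the preset correlation, 0 with an estimated correlation, and fry 2.

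**Figure D3:**
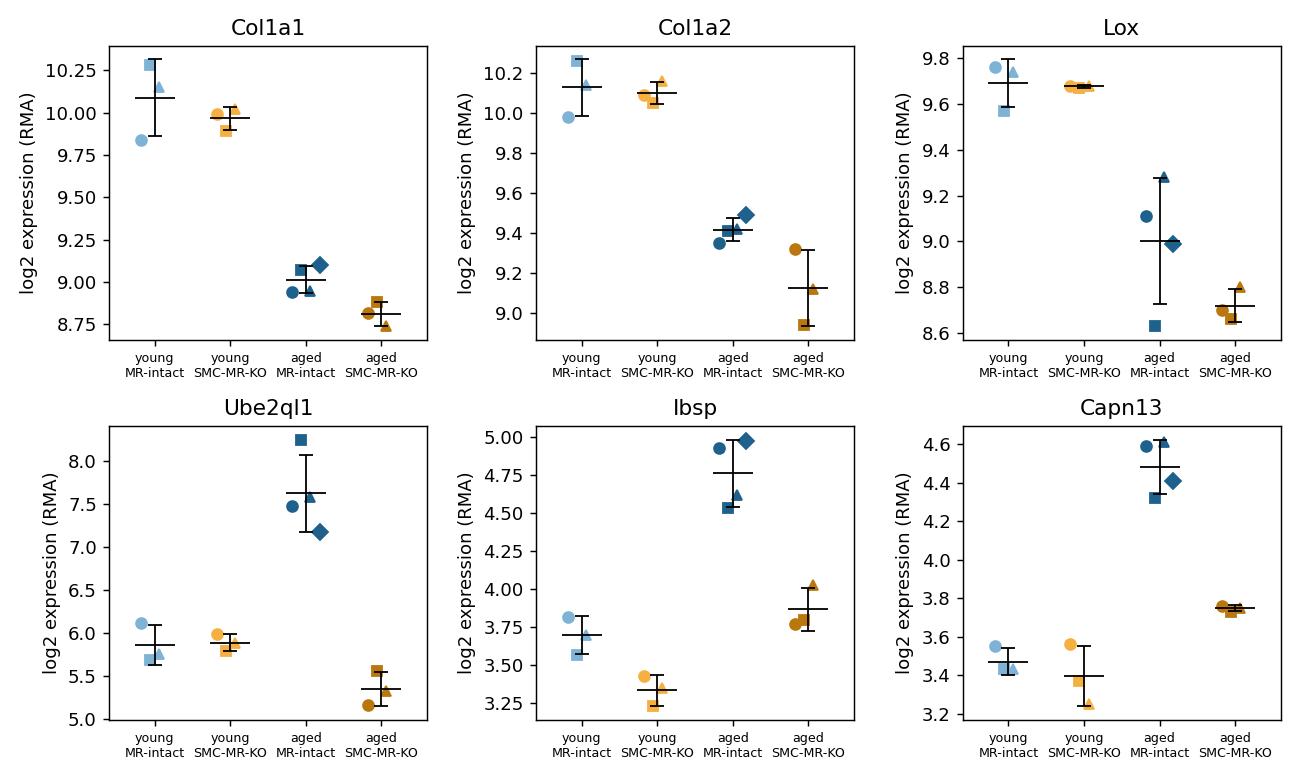
Log2 expression of Col1a1, Col1a2, Lox, Ube2ql1, Ibsp and Capn13 on each array, by group; bars mark the mean and error bars 1 SD (n = 3, 3, 4 and 3), and marker shape gives the replicate number. Ube2ql1 averages 7.62 in aged MR-intact and 5.35 in aged knockout aorta, while Col1a1 averages 9.01 and 8.81 in these groups and 10.09 and 9.97 in the young ones.

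In knockout aorta, genes called lower with age included collagen and other matrix genes, and those called higher included immunoglobulin and lymphocyte genes. Col1a1 changed by -1.15 (SE 0.10, limma adjusted p = 0.000765, n = 3 and 3) and Col1a2 by -0.97 (SE 0.10, limma adjusted p = 0.00175). Lox changed by -0.96 (SE 0.13, limma adjusted p = 0.00911) and Adamts2 by -0.86 (SE 0.08, limma adjusted p = 0.000765). Hhip, which binds and inhibits hedgehog ligands, had the largest decrease of the genes named, -1.21 (SE 0.14, limma adjusted p = 0.00259). Also lower were Pdgfrl (-0.97), the protease Bace2 (-0.93), the fibroblast gene Pi16 (-0.91), Olfml2b (-0.90), complement C7 (-0.83), the matrix protein Fbln1 (-0.83) and Rasl11b (-0.83). Among genes that rose, Ighg1, an immunoglobulin heavy chain gene, changed by 5.58 (SE 0.89, limma adjusted p = 0.0186) and Ighm by 2.31 (SE 0.33, limma adjusted p = 0.0123). The light chain segments Igkv3-4, Igkv10-96, Igkv12-46, Igkv8-21, Igkv8-24, Igkv6-20 and Igkv6-13 rose by 5.23, 4.99, 4.82, 4.27, 3.96, 2.40 and 1.97, although nearly identical segments share sequence, so single segments are uncertain. Cd3g, a part of the T cell receptor complex, rose by 1.76, Slamf7, a receptor of plasma and natural killer cells, by 1.72 and the macrophage lectin gene Cd209b by 1.70.

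In all, 156 genes were called for aging in knockout aorta, 67 higher and 89 lower, with a median absolute log2 change of 0.62. These calls take part of their spread from the MR-intact groups, which varied less than the aged knockout arrays, so the p-values may be too small. All 156 had arrays that did not overlap between the groups, as did 16.4% of all genes, where chance gives 10%. Without aged knockout replicates 1 and 2, an alternative chosen after seeing the data that leaves 1 aged knockout array and takes the spread from the other groups, 51 genes were called (32 higher, 19 lower), of which 21 were among the 156. The balance turned to 152 higher and 136 lower (288 in all) and to 577 higher and 308 lower (885 in all) without aged knockout replicates 1 and 3, and to 148 higher and 63 lower (211 in all) without young knockout replicate 3. The count was 28 (6 higher, 22 lower) and 14 (3 higher, 11 lower) without young knockout replicates 1 and 2, 271 (100 higher, 171 lower) after a second quantile normalization, 241 without the dimmest tercile of features and 1 with only these groups in the fit. Of the 156, 11 had a lower group mean below the lower quartile of every array compared (3.99 to 4.14), among them Igkv3-4 (2.99), Igkv6-13 (3.20) and Igkv8-24 (2.21). Centring each array on its median gave 69 higher and 143 lower, and the B lymphocyte list mean as a covariate, also chosen after seeing the data, left 7. Of the 24 genes named, Hhip, Col1a1, Col1a2, Pdgfrl, Bace2, Adamts2 and Fbln1 were called whichever array was left out; the other 17 lost the call at least once, 4, 4 and 0 of them without aged knockout replicates 1, 2 and 3, and 13, 17 and 1 without young knockout replicates 1, 2 and 3.

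Matrix lists were lower with age in knockout aorta also with an estimated correlation. Of 35 fibrillar collagen and cross-linking genes 15 fell (26 when adjusted over the list alone), with a median of -0.46; besides those above, Col3a1 changed by -0.80 and Col6a1 by -0.65 (camera adjusted p = 2.93e-27; adjusted p = 0.00658 with an estimated correlation). Of 20 basement membrane genes 5 fell (14 when adjusted over the list alone), among them Pxdn (-0.68), Agrn (-0.55) and the type IV collagen chain gene Col4a2 (-0.48), with a median of -0.35 (adjusted p = 0.0091 with an estimated correlation). Of 20 elastic fibre genes 5 fell (1 higher and 15 lower when adjusted over the list alone), among them Fbln2 (-0.52), Mfap2 (-0.47) and Ltbp3 (-0.40), with a median of -0.46 (adjusted p = 0.0402 with an estimated correlation). Among 36 matrix proteases and inhibitors 5 fell, including Mmp2 (-0.59), and Mmp3 rose by 0.79 (3 higher and 10 lower when adjusted over the list alone; median -0.14; adjusted p = 0.0091 with an estimated correlation). Of 42 vasoactive receptor genes 1 fell, the endothelin receptor gene Ednra, at -0.71 (1 higher and 9 lower when adjusted over the list alone; median -0.19; adjusted p = 0.0091 with an estimated correlation). Of 20 fibroblast markers 5 fell, among them Pi16, Entpd2 (-0.74) and Clec3b (-0.46) (14 when adjusted over the list alone; median -0.43; adjusted p = 0.0368 with an estimated correlation). TGF-beta and BMP genes had a median of -0.24 with 0 of 33 called (10 lower when adjusted over the list alone; adjusted p = 0.0368 with an estimated correlation).

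These 7 were the lists that held with an estimated correlation, of 22 called at the preset correlation in this contrast, and fry called 12. The collagen list stayed below 0.05 whichever array was left out (adjusted p = 0.00937 to 0.0273), and without both aged knockout replicates 1 and 2, with 1 array left in that group, its adjusted p was 0.0849. With an estimated correlation the basement membrane list was lost without aged knockout replicate 3 (adjusted p = 0.0526), the vasoactive list without replicate 2 (0.0503), and the protease list without replicates 2 (0.0503) and 3 (0.0526). The elastic fibre list was lost without aged replicate 3 (0.0746) and young replicates 2 (0.0545) and 3 (0.0817). The TGF-beta list was lost in these runs and without aged replicate 2 (0.0869). The fibroblast list was lost without aged replicates 1, 2 and 3 (0.063, 0.0503 and 0.063) and young replicates 2 and 3 (0.0545 and 0.0817).

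Lymphocyte marker lists were higher with age in knockout aorta at the preset correlation, but neither was called with an estimated correlation. Of 20 B lymphocyte and plasma cell genes 2 rose, Ighg1 and Ighm, and 18 when adjusted over the list alone, with a median of 1.70 (camera adjusted p = 4.34e-15; adjusted p = 0.185 with an estimated correlation); the median was 1.09 without aged knockout replicate 1. Of 19 T lymphocyte genes 2 rose, Cd3g and Icos, a costimulatory receptor (1.25), and 15 when adjusted over the list alone, with a median of 0.92 (camera adjusted p = 2.44e-11; adjusted p = 0.193 with an estimated correlation). The ages overlapped on the T lymphocyte list, where young knockout replicate 3 averaged 5.79 and aged knockout replicate 3 averaged 5.58, and on the B lymphocyte list these arrays were close, at 6.84 and 7.04. Of 85 immunoglobulin features 14 rose, and their median was 1.99. Cell cycle genes had a median of 0.56 with 0 of 34 called (12 higher when adjusted over the list alone; camera adjusted p = 4.35e-12; adjusted p = 0.298 with an estimated correlation), and their median was 0.19 without aged knockout replicate 1, which had a list mean of 6.42 against 5.17 and 5.37 on replicates 2 and 3. Of 24 macrophage markers Ms4a7 rose by 0.77 (7 higher when adjusted over the list alone; median 0.17; camera adjusted p = 0.000154; adjusted p = 0.298 with an estimated correlation), with a median of 0.11 without aged knockout replicate 2. Contractile smooth muscle genes had a median of -0.30 with 0 of 30 called (1 higher when adjusted over the list alone; camera adjusted p = 1.76e-07; adjusted p = 0.298 with an estimated correlation), and their median was -0.46 without aged knockout replicate 1 and -0.11 without replicate 2. Skeletal and cardiac muscle markers had medians of -0.78 and -0.65 (camera adjusted p = 0.000167 and 0.00027; adjusted p = 0.521 and adjusted p = 0.412 with an estimated correlation); without young knockout replicate 3 the skeletal muscle median was -0.25 (camera adjusted p = 0.236). Liver markers had a median of 0.40 (camera adjusted p = 0.0158; adjusted p = 0.585 with an estimated correlation), which turned to -0.03 without aged knockout replicate 2 (camera adjusted p = 0.869). Endothelial markers had a median of -0.19 (camera adjusted p = 0.000551; adjusted p = 0.477 with an estimated correlation), and -0.08 without aged knockout replicate 3 (camera adjusted p = 0.0604).

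The aging contrasts of both genotypes share no array, and genes called in each overlapped. The title letter differed with age in both contrasts, so an effect of what it marks cannot be told apart from age. Genes lower in both were Col1a1, Col1a2, Col3a1, Lox, Adamts2, Bace2, Fbln1 and Slc4a10, 8 against 0.0503 expected of independent lists. Genes higher in both were Apod, Cdh9, Mmp3, Pisd-ps1, Serinc2 and Vwc2, 6 against 0.12 expected. Both sets of calls use the same estimate of each gene's spread, so a gene with a small spread is favoured in both. Genes that move together were also counted singly. The expected counts are therefore too low and do not measure chance. All 12 genes lower in MR-intact aorta and 35 of the 38 higher ones had the same sign in knockout aorta, and 85 of 89 lower and 54 of 67 higher genes in knockout aorta had the same sign in MR-intact aorta. Across all 21225 genes, which are not independent replicates, the log2 changes correlated at r = 0.359 (Spearman 0.192). Under 100 permutations of the age labels within genotype r ranged from -0.411 to 0.481, and 3 were as high (11 for Spearman).

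No gene was called for the knockout in young aorta, where 0 of 21225 passed the limma test, the smallest adjusted p was 1 and 549 genes had an unadjusted p under 0.05. Those are 2.59% of genes, fewer than the share of 0.05 that chance gives on average. The shared spread takes in the wider aged groups, which may make this test too strict. The absence of calls therefore does not show that the knockout has no effect in young aorta. Every alternative fit also called 0. The genes with the smallest p, which do not pass, included Ccl22, a chemokine, at 0.56, the immune checkpoint ligand gene Cd274 at 0.31, calmodulin gene Calm2 at 0.34, Ugt2b38 at 0.58, Neto2 at 0.53, Fam170a at 0.37, Prss54 at 0.37, Drd5 at 0.31, Psg28 at -0.43 and Zfp617 at -0.46. Oxidative phosphorylation genes had a median of -0.10 (camera adjusted p = 2.35e-07; adjusted p = 0.895 with an estimated correlation). Corticosteroid receptor targets had a median of -0.13 with 0 of 25 called and 0 when adjusted over the list alone (camera adjusted p = 0.000737; adjusted p = 0.583 with an estimated correlation). Without young MR-intact replicate 2 their camera adjusted p was 0.0588, and without young knockout replicate 3 their median was -0.06. Cardiac and skeletal muscle markers had medians of -0.74 and -0.55 in the same arrays (camera adjusted p = 1.17e-05 and 0.000127; adjusted p = 0.734 and adjusted p = 0.895 with an estimated correlation). The skeletal muscle median was -0.01, -0.36 and -1.22 without young MR-intact replicates 1, 2 and 3, and -0.30, -0.27 and -1.16 without young knockout replicates 1, 2 and 3 (camera adjusted p = 0.753 without MR-intact replicate 1, 0.0769 and 0.0849 without knockout replicates 1 and 2). The cardiac muscle median was -0.24, -0.33 and -1.45 without young MR-intact replicates 1, 2 and 3, and -0.33 and -1.14 without young knockout replicates 1 and 2 (camera adjusted p = 0.0874 without MR-intact replicate 1). Camera called 7 of 36 lists at the preset correlation, 0 with an estimated one, and fry called 0.

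In aged aorta, Ube2ql1, Ibsp and Capn13, which rose with age in MR-intact mice, were lower in the knockout. Ube2ql1 changed by -2.28 (SE 0.20, limma adjusted p = 0.00148, n = 3 and 4), from 7.62 ± 0.45 in MR-intact to 5.35 ± 0.20 in knockout aorta. Ibsp changed by -0.90 (SE 0.12, limma adjusted p = 0.0204), from 4.76 ± 0.22 to 3.87 ± 0.14, and Capn13 by -0.74 (SE 0.09, limma adjusted p = 0.0134), from 4.48 ± 0.14 to 3.75 ± 0.01. From young to aged knockout aorta the means of Ibsp and Capn13 still rose, from 3.34 to 3.87 and from 3.39 to 3.75. Ube2ql1 went from 5.89 to 5.35 there. In young aorta Ibsp already read 3.34 ± 0.1 in knockout and 3.7 ± 0.13 in MR-intact arrays, without being called. The neutral amino acid transporter gene Slc1a4 was also lower in the aged knockout, at -0.59 (SE 0.08, limma adjusted p = 0.0212). Higher were Cxcr2, a neutrophil chemokine receptor, at 1.17 (SE 0.17, limma adjusted p = 0.0244), and the immunoglobulin light chain segments Igkv8-24 at 3.34 (SE 0.50, limma adjusted p = 0.0372) and Igkv6-13 at 2.24 (SE 0.30, limma adjusted p = 0.0212), whose identity among nearly identical segments is uncertain. The remaining called genes, named after their values were seen, were Igkv4-69 at 3.30, the small nucleolar RNAs Snord34, Snord53 and Snord35a at 1.31, 1.02 and 0.89, and Pramel19 at 0.72. Tnfrsf11b, at -0.68 (limma adjusted p = 0.0518), did not pass.

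In all, 12 genes were called for the knockout in aged aorta, 8 higher and 4 lower, while 3744 had an unadjusted p under 0.05. These calls take part of their spread from the young groups, which varied less than the aged knockout arrays, so the p-values may be too small. All 12 had arrays that did not overlap, as did 10.4% of all genes, where chance gives 5.71%. Other divisions of the 7 arrays into 3 and 4 called up to 20 genes, so chance cannot be excluded for this count. The count was 3 and 6 without aged MR-intact replicates 1 and 3, and 89 (50 higher, 39 lower), 26 (19 higher, 7 lower) and 1442 (797 higher, 645 lower) without aged knockout replicates 1, 2 and 3. Without aged MR-intact replicate 2 it was 196, with the balance turned to 52 higher and 144 lower. Without both aged knockout replicates 1 and 2, chosen after seeing the data and leaving 1 aged knockout array, it was 10, of which 2 were among the 12, and with the B lymphocyte covariate 1, which was not among them. The count was 23 (11 higher, 12 lower) with an intensity trend and robust prior, 24 (9 higher, 15 lower) after a second quantile normalization and 115 (51 higher, 64 lower) with centred arrays. It was 5 each without the dimmest tercile and with array weights, 1 with neighbouring title numbers as a block, and 0 with only these groups in the fit. The lower group mean of 7 of the 12 lay below the lower quartile of every array compared (3.89 to 4.14), at 3.87 for Ibsp, 3.75 for Capn13, 3.12 for Cxcr2, 2.93 for Igkv6-13, 2.83 for Igkv8-24, 2.68 for Pramel19 and 2.35 for Igkv4-69, and how far these levels stand above background is not known. The filter on the dimmest tercile removed these 7 and left Ube2ql1, Slc1a4, Snord34, Snord53 and Snord35a. Of the 7 genes named by rule, Ube2ql1 was called whichever array was left out; 6, 0, 3 and 2 of the others lost the call without aged MR-intact replicates 1 to 4, and 0, 1 and 0 without aged knockout replicates 1 to 3.

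At the preset correlation, lists of matrix and contractile genes were lower, and lymphocyte lists higher, in aged knockout than in aged MR-intact aorta. B lymphocyte and plasma cell genes had a median of 2.09 with 0 of 20 called over all genes and 20 higher when adjusted over the list alone (camera adjusted p = 4.97e-17; adjusted p = 0.136 with an estimated correlation). T lymphocyte genes had a median of 0.97 with 0 of 19 called (16 higher when adjusted over the list alone; camera adjusted p = 1.16e-11; adjusted p = 0.141 with an estimated correlation), and 0.64 without aged knockout replicate 1. Contractile smooth muscle genes had a median of -0.45 with 0 of 30 called (22 lower when adjusted over the list alone; camera adjusted p = 2.67e-12; adjusted p = 0.14 with an estimated correlation), and -0.23 without aged knockout replicate 2. Members with the smallest p were Nexn (-0.76), Pgm5 (-0.64), the actin-binding gene Cald1 (-0.46) and the myosin light chain kinase gene Mylk (-0.35), none of which passed over all genes. Fibrillar collagen genes had a median of -0.27 with 0 of 35 called (18 lower when adjusted over the list alone; adjusted p = 0.0457 with an estimated correlation). Basement membrane genes had a median of -0.23 with 0 of 20 called (11 lower when adjusted over the list alone; adjusted p = 0.0457 with an estimated correlation). Fibroblast markers moved with these lists, with a median of -0.31, 0 of 20 called and 9 lower when adjusted over the list alone (camera adjusted p = 6.95e-08; adjusted p = 0.136 with an estimated correlation), and averaged 9.17, 8.90 and 9.20 on aged knockout and 9.27 to 9.42 on aged MR-intact arrays. Vasoactive receptor genes had a median of -0.14 with 0 of 42 called (11 lower when adjusted over the list alone; adjusted p = 0.0457 with an estimated correlation). Matrix proteases and inhibitors had a median of -0.11 with 0 of 36 called (1 higher and 11 lower when adjusted over the list alone; adjusted p = 0.0356 with an estimated correlation). Of 25 osteochondrogenic genes 1 was lower, Ibsp (4 when adjusted over the list alone; median -0.10; camera adjusted p = 0.00562; adjusted p = 0.0617 with an estimated correlation), and the median was -0.05 without aged MR-intact replicate 1. Corticosteroid receptor targets had a median of -0.05 with 0 of 25 called (1 lower when adjusted over the list alone; camera adjusted p = 0.0943). Liver markers were above 0 in 12 of 12, with a median of 0.46 (camera adjusted p = 0.00312; adjusted p = 0.503 with an estimated correlation), and of 0.05 without aged knockout replicate 2 (camera adjusted p = 0.507).

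Camera called 20 of 36 lists in this contrast, fry called 15, and only the collagen, basement membrane, vasoactive and protease lists held with an estimated correlation. Without aged knockout replicate 3 the adjusted p of each was 0.156, and without both replicates 1 and 2 it was 0.0944 for collagen, basement membrane and proteases and 0.193 for the vasoactive list. Without replicate 1 it was 0.0892 for collagen, basement membrane and proteases and 0.0993 for the vasoactive list, and without replicate 2 it was 0.0593 for each of the 4 lists. Without aged MR-intact replicate 1 it was 0.0551, 0.0689 and 0.0551 for the collagen, basement membrane and vasoactive lists, and without replicate 3 it was 0.0606 for each of these.

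**Figure D4:**
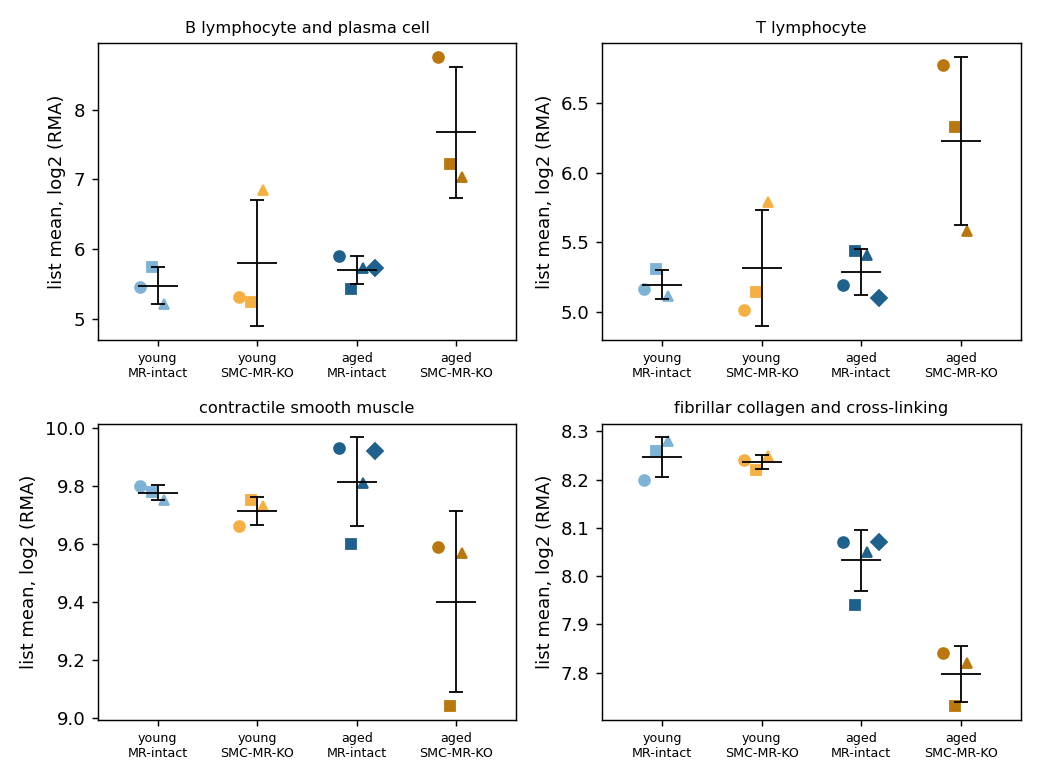
Mean log2 expression of the members of 4 gene lists (B lymphocyte and plasma cell, T lymphocyte, contractile smooth muscle, fibrillar collagen) on each array, by group; bars mark the mean and error bars 1 SD (n = 3, 3, 4 and 3), and marker shape gives the replicate number. The B lymphocyte list reads 7.04 to 8.76 on aged knockout arrays and 5.42 to 5.90 on aged MR-intact arrays.

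Averaged over both ages, Ube2ql1 and Ibsp had the smallest adjusted p for the knockout, without passing. Ube2ql1 differed by -1.12 and Ibsp by -0.63 (limma adjusted p = 0.0819 for each). Also among the 10 genes of smallest p were Cd274 at 0.35, Ccl22 at 0.49, Capn13 at -0.41, Nr3c2 at -0.55, Cxcr2 at 0.68, Igkv6-13 at 1.23 and Fam107a at -0.52. Limma called 0 genes, with 2315 at an unadjusted p under 0.05. It called 4 with array weights and 1 with neighbouring title numbers as a block. It called 2 and 1 without aged MR-intact replicates 2 and 4, and 292 (253 higher, 39 lower) without aged knockout replicate 3. Corticosteroid receptor targets had a median of -0.10 with 0 of 25 called and 0 when adjusted over the list alone (camera adjusted p = 0.00127; adjusted p = 0.148 with an estimated correlation), and of -0.06 without aged knockout replicate 1 or young MR-intact replicate 1. Of 36 lists camera called 21 and fry 5, and with an estimated correlation only matrix proteases and inhibitors held (median -0.08; adjusted p = 0.024 with an estimated correlation). That call was lost without aged knockout replicates 1, 2 and 3 (adjusted p = 0.0866, 0.0884 and 0.192), young MR-intact replicate 2 (0.0539), young knockout replicate 3 (0.0631), and both aged knockout replicates 1 and 2 (0.127).

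For the difference of aging between the genotypes, Ube2ql1 came closest to the threshold: its mean went from 5.86 to 7.62 with age in MR-intact aorta and from 5.89 to 5.35 in knockout aorta. Its interaction was -2.30 (SE 0.30, limma adjusted p = 0.0843), and without aged knockout replicate 3 its adjusted p was 0.039. The next genes, each with limma adjusted p = 0.609, were Slc1a4 (-0.62), Smpdl3b (-0.62), Capn13 (-0.66), H2bc9 (0.74), the heat shock protein gene Hspa8 (1.54), Uchl3 (0.60), Igkv6-13 (2.02), Igkv8-24 (3.30) and Cdc42bpa (-0.63). Limma called 0 genes, with 1723 at an unadjusted p under 0.05. It called 1 with array weights and 1 with neighbouring title numbers as a block. Without each of aged MR-intact replicates 2 and 4 it called 1, and without aged knockout replicate 3 it called 16. Of 36 lists camera called 22, fry 6 and camera with an estimated correlation 0. B lymphocyte and plasma cell genes had a median difference of 1.70 (5 higher when adjusted over the list alone; camera adjusted p = 4.95e-12; adjusted p = 0.268 with an estimated correlation), and 1.11 without aged knockout replicate 1. Fibrillar collagen genes had a median difference of -0.23 (camera adjusted p = 1.62e-08; adjusted p = 0.0895 with an estimated correlation) and contractile smooth muscle genes -0.39 (camera adjusted p = 1.78e-07; adjusted p = 0.311 with an estimated correlation), the latter -0.20 without aged knockout replicate 2. Fibroblast markers had a median difference of -0.34 (camera adjusted p = 1.38e-06; adjusted p = 0.207 with an estimated correlation), and -0.22 without aged knockout replicate 2.

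Genes chosen for aging in MR-intact aorta tended to differ in the opposite direction in the aged knockout. With the 4 aged MR-intact arrays divided so that the contrasts shared no array, the slope of the knockout effect on the aging effect over 25 to 200 genes was -0.33 across 6 divisions (-0.42 to -0.21), with 68.1% of genes of opposite sign. The genes were those called for aging in a division, or the 200 of smallest p where too few were called. In 50 simulations of an unchanged knockout the slope was 0.07 (0.03 to 0.13), with 36.5% opposite. The simulated knockout was drawn around the mean of all 4 aged MR-intact arrays, including those of the aging effect, which pushes the slope upward. Noise was also independent between genes, so this range does not measure chance for -0.33. The slope was -0.23, -0.18 and -0.10 without young MR-intact replicates 1, 2 and 3, and -0.23 and -0.47 without aged MR-intact replicates 1 and 2. With all arrays in both contrasts it was -0.46, with 82% opposite (simulated 0 and 50.9%). Those simulations drew the knockout around the measured aged MR-intact means, which sets the slope near 0 in advance. The effect of shared arrays was left out, so they are no reference for -0.46. With the arrays divided, the slope was -0.23 over the 200 genes of smallest p and -0.09 over 1000 genes. The genes called in both contrasts, Capn13, Ibsp and Ube2ql1, all had opposite signs. Both contrasts use the same aged MR-intact arrays with opposite sign, which by itself favours this.

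The authors' deposited table gives fold changes for 4 comparisons. Set against the mean differences of the deposited log2 values across 21225 genes, the folds in the authors' deposited table correlated at r = 0.969 for the young knockout, 0.99 for the aged knockout and 0.989 for aging in MR-intact aorta. The comparison that the authors' deposited table heads as aged knockout against young MR-intact correlated at 0.905 with that difference and at 0.987 with aged against young knockout. The p-values in the authors' deposited table lay under 0.05 for 971, 2577, 2466 and 2198 genes in these comparisons, and after Benjamini-Hochberg adjustment for 0, 0, 47 and 1.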

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

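Tests of other divisions of the arrays were planned before their results were seen; the tests of lymphocyte, contractile and fibroblast content, the list medians with arrays left out, and the choice of fry for differences between the genotypes, were made only after the results were seen.

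Among the 4 aged MR-intact arrays, 5 of 99 values examined had 1 array far from the others relative to the group's range, and chance flags about 1 in 20 groups. Igkv6-13, an immunoglobulin light chain segment that is higher in the aged knockout, read 3.3 on replicate 3 and 2.77 to 2.83 on the others. Ccl22 read 3.29 on replicate 4 against 3.74 to 3.77, and Prss54 read 3.67 on replicate 4 against 3.77 to 3.79. Slc1a4, lower in the aged knockout, read 6.8 on replicate 2 against 6.93 to 6.95. The mean of the fibrillar collagen and cross-linking list read 7.94 on replicate 2 against 8.05 to 8.07.

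A difference of the aging effect between the genotypes marked 6 lists, all lower with age in knockout relative to MR-intact aorta by fry (adjusted p = 0.0279 each). Their median differences were -0.23 for fibrillar collagen and cross-linking, -0.26 for basement membrane, -0.14 for matrix proteases and inhibitors, -0.21 for vasoactive receptors, -0.21 for TGF-beta and BMP signalling and -0.10 for osteochondrogenic genes. Camera with an estimated correlation, which compares each list with the other genes, gave adjusted p = 0.0895 for all 6. Fibroblast markers moved with them, with a median difference of -0.34 (-0.22 without aged knockout replicate 2; fry adjusted p = 0.0971). The protease median was -0.08 without aged MR-intact replicate 3 or aged knockout replicate 3, and -0.06 without aged knockout replicate 1 or young knockout replicate 2. The osteochondrogenic median was -0.04 and -0.17 without aged MR-intact replicate 2 and aged knockout replicate 3, and -0.19 and -0.05 without young MR-intact replicate 1 and young knockout replicate 2.

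Lymphocyte lists were higher in aged knockout than in aged MR-intact aorta at the preset correlation, with a B lymphocyte list median of 2.09 and Ighg1 at 10.62 ± 1.86 (SD, n = 3). Over all genes 0 of 20 B and 0 of 19 T lymphocyte genes were called, and with an estimated correlation neither list was (adjusted p = 0.136 and adjusted p = 0.141). No gene of the B or T lymphocyte lists is on another list. Lymphoid tissue on 1 array alone is argued against, but only narrowly. The lowest median on leaving out an aged knockout array was 1.45 (without replicate 1, spread between arrays 0.94), and the others were 2.32 and 2.46. That lowest median exceeded the cut-off, which was set after the results were seen, by barely more than the spread. The T lymphocyte list of every aged knockout array lay above every aged MR-intact array, by at least 0.14 (spread 0.61), which is consistent with lymphoid cells of several kinds. Cells in the vessel wall that differ with genotype and lymphoid tissue left on the vessel at dissection both stay open, and neither was tested.

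The contractile smooth muscle list was lower in aged knockout than in aged MR-intact aorta at the preset correlation, with a median of -0.45. Over all genes 0 of 30 members were called, and the list was not called with an estimated correlation (adjusted p = 0.14). Dilution by lymphocytes would lower endothelial genes alike: contractile minus endothelial list means differed by -0.49 between the groups (two-sided exact permutation p = 0.114, n = 3 and 4), and by -0.64, -0.18 and -0.65 without aged knockout replicates 1, 2 and 3, so dilution cannot be told apart from a loss of contractile transcripts with these few arrays. Aged knockout replicate 2 may carry part of the pattern. Without it the median was -0.23, and without replicates 1 and 3 it was -0.55 and -0.53, against an SD of 0.15 between aged MR-intact arrays, so a single-array origin also stays open.

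The collagen list was lower in aged aorta of both genotypes at the preset correlation. With age 4 of 35 members fell in MR-intact aorta, where the list was not called with an estimated correlation (adjusted p = 0.0772), and 15 fell in knockout aorta, where it was (adjusted p = 0.00658). Fewer fibroblasts cannot be told apart from lower expression per cell. In MR-intact aorta 15 fibroblast markers without matrix roles had a median of -0.18 and the 35 collagen list genes -0.14 (difference -0.04). In knockout aorta the medians were -0.43 and -0.46 (difference 0.03). An SE of 0.05 in both contrasts is that of the difference of list means, not of medians. An equal fall is what fewer fibroblasts would give, but it would also follow if both lists were lowered together in the same cells, and the fibroblast list in MR-intact aorta was not called with an estimated correlation (adjusted p = 0.38). Col1a1, Col1a2 and Col3a1 fell further, with medians of -0.77 and -0.97, but they are the strongest genes of the pattern and exclude nothing.

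Other divisions of the same arrays bear on the counts of called genes. For aging in MR-intact aorta, of 35 divisions only the real 1 called as many as 50, and the highest other called 0. This argues against chance but does not exclude it. No smaller share can be had from 35 divisions, and several contrasts were tested in this way. For aging in knockout aorta, 156 were called and 35 in the highest other of 10 divisions (1 as many, the real division), and these divisions are too few for a share under 0.05. For the knockout in young aorta, 0 were called and 15 in the highest other. A count of 0 is reached by every division (10 as many), so this test could not exclude chance. For the knockout in aged aorta chance cannot be excluded: 3 of 35 divisions called as many as 12, and the highest other called 20. For the averaged knockout and for the difference of aging, 0 were called, so all 100 drawn divisions necessarily called as many, and the highest others called 4 and 3.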

How the results depend on the processing

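Chosen only after the results were seen were the runs without aged knockout replicates 1 and 2, those with the B lymphocyte covariate, the fit of the 6 title digit arrays without the block, and the runs of the list tests and of the slope with arrays left out.

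For called genes that were named by rule or are on a list, 1455 values were tried under other settings. Of these, 967 kept the call, 488 lost it and 0 changed sign. The remaining called genes were not counted here. Among called lists the direction turned without aged knockout replicate 2 for liver markers (aging in knockout aorta, median -0.03) and for Schwann and neuronal markers (aged knockout and averaged knockout, median 0 in both). Without young MR-intact replicate 1 the skeletal muscle median in the averaged knockout went from -0.19 (camera adjusted p = 0.0396) to 0.03 (0.858), with the test still downward, and the median of oxidant and antioxidant enzymes in the young knockout from -0.04 to 0. Scalings moved array medians by at most 0.083 log2 units. The young knockout count was 0 in every setting. Nr3c2 stayed between -0.62 and -0.50, and the correlation of aging effects between 0.272 and 0.461. The number of arrays and the aged knockout spread limit the precision, and the cause of the other changes was not tested.

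With arrays left out in turn the counts ran from 14 to 104 (aging, MR-intact, 50), 14 to 885 (aging, knockout, 156), 3 to 1442 (knockout, aged, 12), 0 to 292 (averaged, 0) and 0 to 16 (difference, 0), and list calls from 102 to 115 (all, 107) and from 2 to 18 (estimated correlation, 12). The slope of aging genes ran from -0.47 to -0.10. Array weights gave 489 for aging in MR-intact aorta, 5 for the aged knockout, 4 averaged and 1 for the difference. A second quantile normalization gave 271 for aging in knockout aorta and 24 for the aged knockout, and centring gave 115 for the latter. Without the dimmest tercile of features these were 241 and 5. Trend and robust prior gave 23 for the aged knockout. With only the groups compared, aging in knockout aorta gave 1 and the aged knockout 0. Without aged knockout replicates 1 and 2, with 1 array left in that group, the counts were 51 for aging in knockout aorta, 10 for the aged knockout, 1 averaged, 1 for the difference, and 0 list calls with an estimated correlation. The B lymphocyte covariate left 7 and 1 for aging in knockout aorta and the aged knockout. Over all contrasts, 107 list calls became 12 with an estimated correlation and 40 with fry. The slope of -0.33 became -0.23 with 200 genes, -0.09 with 1000 and -0.46 with all aged MR-intact arrays in both contrasts.

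The title digit as a replicate block gave 1 gene for aging in MR-intact aorta, and the same 6 arrays without the block 0, so the fall from 50 goes with the smaller set of arrays. Deviations of arrays with the same digit correlated at -0.07 to 0.08 over 3 pairs, against -0.14 to 0.2 for other pairs. Those with neighbouring title numbers correlated at -0.28 to 0.28 over 6 pairs, of which 2 exceeded 0.1, against -0.28 to 0.4 for other pairs. So few values neither show nor exclude a pairing of arrays by these numbers. Neighbouring numbers as a block gave 1 for the aged knockout, 1 averaged and 1 for the difference (Ube2ql1), 0 for the young knockout, and 74 against 70 list calls in the knockout contrasts.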

Other observations

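The runs of the list tests with arrays left out, and the classes of small nucleolar RNA, histone and microRNA genes, were chosen only after the results were seen.

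Oxidative phosphorylation genes were above 0 in 37 of 38 with age in knockout aorta (median 0.12, camera adjusted p = 9.54e-06; adjusted p = 0.521 with an estimated correlation; median 0.19 and 0.07 without aged knockout replicates 1 and 3), but had a median of -0.05 with age in MR-intact aorta (camera adjusted p = 0.00107; adjusted p = 0.768 with an estimated correlation). That median was -0.02 without aged MR-intact replicate 1 (camera adjusted p = 0.284), -0.11 without replicate 2 and -0.08 without young MR-intact replicate 3. The difference between the genotypes had a median of 0.22 (camera adjusted p = 8.65e-10; adjusted p = 0.33 with an estimated correlation). Lipid metabolism genes had a median of -0.13 with age in MR-intact aorta (camera adjusted p = 1.99e-05; adjusted p = 0.475 with an estimated correlation), and of -0.05 without aged MR-intact replicate 1. White adipocyte markers had -0.08 there (camera adjusted p = 0.00745; adjusted p = 0.489 with an estimated correlation; camera adjusted p = 0.0963 and 0.0555 without aged and young MR-intact replicate 1). Brown adipocyte markers had 0.22 with age in knockout aorta (camera adjusted p = 0.0127; adjusted p = 0.521 with an estimated correlation), with camera adjusted p = 0.0883 and 0.131 without aged knockout replicates 2 and 3 and 0.0652 without young knockout replicate 3. Without aged knockout replicate 2 the median was 0.14. Circadian clock genes, which follow the hour of tissue collection, had 0 of 20 called with age in MR-intact aorta, but 6 higher and 4 lower when adjusted over the list alone (median 0.18, camera adjusted p = 0.0799). In the aged knockout their median was -0.24 (camera adjusted p = 0.00271; adjusted p = 0.136 with an estimated correlation).

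Integrin and focal adhesion genes had a median of -0.26 in the aged knockout relative to aged MR-intact aorta, with 0 of 34 called and 1 higher and 17 lower when adjusted over the list alone (camera adjusted p = 3.32e-09; adjusted p = 0.14 with an estimated correlation), and -0.15 without aged knockout replicate 2. Ion channel and calcium handling genes had a median of -0.26, with 0 of 39 called and 4 lower when adjusted over the list alone (camera adjusted p = 1.28e-06; adjusted p = 0.14 with an estimated correlation); members with the smallest p were Cacna2d1 (-0.56) and the potassium channel gene Kcnma1 (-0.61), and the median was -0.13 without aged knockout replicate 2. Schwann and neuronal markers had a median of 0.32 (camera adjusted p = 0.0273; adjusted p = 0.633 with an estimated correlation), with a list mean of 6.69 on aged knockout replicate 2 and 5.64 on the other two. The median was 0 without aged knockout replicate 2 (camera adjusted p = 0.43), where the direction of the test turned, 0.55 without replicate 3, and 0.29 without aged MR-intact replicate 4 (camera adjusted p = 0.0527). Small nucleolar RNAs had a median of 0.66, with 3 of 48 called and 95.8% above 0; the list means were 6.8, 7.57 and 7.07 on aged knockout and 6.45 to 6.64 on aged MR-intact arrays. Of 54 histone genes 4 rose with age in knockout aorta, with 90.7% above 0, while 312 microRNA features had a median of -0.01.

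Further lists called for the knockout in aged aorta at the preset correlation had 0 members called, and none was called with an estimated correlation. Medians were -0.28 for elastic fibre (camera adjusted p = 1.25e-09; adjusted p = 0.0974 with an estimated correlation), -0.16 for TGF-beta and BMP signalling (camera adjusted p = 1.5e-06; adjusted p = 0.0798 with an estimated correlation) and 0.52 for cell cycle genes (camera adjusted p = 3.61e-09; adjusted p = 0.405 with an estimated correlation), the last 0.17 without aged knockout replicate 1. The oxidative phosphorylation median was 0.12 (camera adjusted p = 0.000194; adjusted p = 0.587 with an estimated correlation), and 0.06, 0.19 and 0.08 without aged MR-intact replicate 1 and aged knockout replicates 1 and 3, the last run losing the call (camera adjusted p = 0.166). White and brown adipocyte markers had medians of 0.11 (camera adjusted p = 0.0316; adjusted p = 0.545 with an estimated correlation) and 0.14 (camera adjusted p = 0.0337; adjusted p = 0.587 with an estimated correlation). Their medians were 0.07 and 0.09 without aged MR-intact replicate 1, and 0.18 and 0.26, 0.10 and 0.05, and 0.06 and 0.11 without aged knockout replicates 1, 2 and 3, with the calls lost in each of these runs except that without aged knockout replicate 1 (camera adjusted p = 0.0763 to 0.298).

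Other lists gave no camera call for the knockout in aged aorta. Medians were -0.05 for the renin-angiotensin-aldosterone system (camera adjusted p = 0.06), 0.03 for oxidant and antioxidant enzymes (0.944; -0.02 with centred arrays), 0.01 for complement (0.974; -0.04 with centred arrays), whose mean of 0.06 and downward test differ in sign, 0.13 for interferon response (0.06), 0 for senescence (0.786), -0.08 for immediate early genes (0.306), 0.05 for the unfolded protein response (0.138), -0.09 for erythroid and platelet genes (0.21) and -0.16 for mesothelial markers (0.961). They were 0.11 for cytokines and chemokines (0.0555), 0.12 for lipid metabolism (0.0943), 0.08 for endothelial (0.626), 0.06 for macrophage (0.929) and 0.17 for skeletal muscle markers (0.974), and 0.03 for cardiac muscle markers (0.769; -0.06 after a second quantile normalization and -0.02 with centred arrays), whose mean of -0.01 and downward test differ from the median in sign. With age in knockout aorta C7 fell and Cfp, properdin, rose by 0.61.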
